A study of Mus musculus with 31 samples.

How the data were processed

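Nuclei of 3 kinds of neurons were isolated from the neocortex of adult male mice aged 8 to 11 weeks, 1 to 2 mice per sample, per the labels' protocols. The method, INTACT, tags the nuclear envelope in cells that express Cre recombinase and captures the tagged nuclei. Camk2a-Cre marked excitatory neurons, PV-Cre marked parvalbumin (PV) interneurons and VIP-Cre marked interneurons that make vasoactive intestinal peptide (VIP). Nuclei of a whole neocortex from 1 wild-type mouse per sample, pelleted without capture, served as the tissue control for RNA. The series holds 31 samples: 8 of nuclear RNA, 6 of whole-genome bisulfite sequencing (MethylC-seq), 6 of ATAC-seq and 11 of ChIP-seq on native chromatin of excitatory neurons. The ChIP-seq samples comprise 2 for each of 4 histone marks and 3 of input. Only the called regions of these assays were deposited in a form analysed here, and the input samples were not used here.

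RNA amounts of 2 to 50 ng were amplified and read for 50 cycles, with ERCC spike-in RNA added to every sample, per the labels' protocols. ATAC-seq used about 50000 nuclei per sample. ATAC-seq and MethylC-seq libraries were read for up to 101 cycles and ChIP-seq libraries for 50 cycles, per the labels. RNA reads were processed with TopHat 1.4.0, RSEM 1.1.20 and bedtools 2.15.0, ATAC-seq reads with cutadapt 1.3, Bowtie2 2.1.0, Picard, HOMER and bedtools 2.15.0, and ChIP-seq reads with Bowtie 0.12.7, SICER 1.1 and bedtools 2.15.0, all on genome build mm10, per the submitters' processing notes. The table of differentially methylated regions names methylpy in its title. The tools behind the other methylation regions, the gene annotation and the strand setting are not given in the sources used here.

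The deposited RNA values are TPM, per the file headers, 1 library per file and 2 libraries per group. The sum that sets the TPM scale includes 92 ERCC sequences, which were left out of all tests, and no scaling between libraries is recorded. The tables list 20502 genes besides the spike-ins. Depth is unknown because TPM keeps no read number, so no interval for counting error was computed for RNA. An exact 0 in such a table can also be an estimate that failed, and genes at 0 are reported as listed at 0. Genes that share sequence with close copies, such as hemoglobins, ribosomal proteins and clustered protocadherins, and genes that overlap on opposite strands are uncertain, because the assignment of reads cannot be checked.

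ATAC-seq, ChIP-seq and methylation files were deposited as positions of called regions without a score, height or methylation level, in 1 list per neuron type or mark. Whether replicates were pooled before calling is not stated. The methylation lists per neuron type hold unmethylated regions (UMRs) and low-methylated regions (LMRs). The table of differentially methylated regions (DMRs) gives each region a code of 5 positions, each 0 or 1, which the file does not explain. The plan was to count DMRs by neuron type. They are therefore reported by position number, and no position is given a cell type.

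Genes with at least 1 TPM in at least 2 of the 8 libraries were tested, 15601 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(TPM + 1) of all 8 libraries together with a variance trend, so that the groups share an estimate of the spread. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1. With a pseudocount of 1, differences of genes at low TPM are understated. In 5 runs, normal data were simulated for 15601 genes from each gene's mean over all 8 libraries and the spread of the fit. In each run 200 genes with a mean log2(TPM + 1) above 3 were changed in PV. Tested for PV against excitatory nuclei, the fit recovered 97% of those changed by 1.5 on the log2 scale. It recovered 99.7% of those changed by 2 and 100% of those changed by 3, with 9.2 false calls per run on average. Recovery of genes at lower TPM was not tested. Which mice stand behind each replicate is not stated beyond 1 to 2 mice per sample. The p-values therefore measure only the spread between these samples, which may be technical.

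Lists of genes were fixed from general knowledge. They cover excitatory identity, GABAergic identity, PV and medial ganglionic eminence, VIP and caudal ganglionic eminence, somatostatin and neurogliaform, astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, vascular, voltage-gated potassium channels, voltage-gated sodium and calcium channels, glutamate receptors, GABA receptors, neuropeptides, neuromodulator receptors, activity-regulated genes, DNA methylation machinery, Polycomb and H3K27 demethylases, progenitor transcription factors, synaptic adhesion, cytosolic ribosomal proteins and mitochondrial-encoded genes. Of the 23 lists, 22 were tested, because none of the mitochondrial-encoded genes is listed in the deposited tables. Each list was tested with limma's camera at a preset correlation of 0.01 in 6 contrasts, with adjustment over 132 tests. Of 51 camera calls, 0 held with a correlation estimated from the data, where 11 had an unadjusted p under 0.05, and 48 held with limma's fry, which asks whether the genes of a list move on balance to the same side. Fry also called 21 list contrasts that camera did not, and its p is given beside those in the text. Of the 346 genes in the lists, 19 stand in more than 1. The shared genes include Kcna1, Kcnc1 and Kcnc2 in the PV and potassium channel lists, Vip, Tac2, Crh, Penk and Cck in the VIP and neuropeptide lists, Sst, Npy and Cort in the somatostatin and neuropeptide lists, and Cnr1, Htr2c and Htr3a in the VIP and neuromodulator lists. Tac1, Nkx2-1, Nrxn3 and Grik3 are also each in 2 lists.

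Genes are named by a rule: in contrasts between neuron types the 6 called genes with the largest difference in each direction whose libraries do not overlap, against neocortex 4 in each direction, skipping symbols made of Gm, Rik or LOC with digits. The Cre driver genes are named as a check of the labels. Also named are up to 4 called members of each list or, with none called, the 2 of highest TPM. Region counts are given for 8 loci. Further list members that did not pass are named with their values alone. Tests, gene lists, the naming rule and the alternatives were set before the data were examined, except the tests on PV libraries and on peak list length in the closing section and the alternatives with equal numbers of the longest UMRs and LMRs and with camera without PV replicate 2 or without the Cre driver genes.

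Regions were compared with bedtools 2.31.1 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. An overlap is at least 1 bp, and the interval code gave the same answer as bedtools for 20000 of 20000 simulated intervals in 10 runs. Exact binomial 95% intervals, which cover counting error only, were computed for shares and are given for part of them, as is the mean of 200 random shifts in which all regions of a chromosome move together. Shares were compared with two-sided Fisher's exact tests, adjusted over families of 15 tests for DMRs against each kind of list, 44 for histone marks and 24 for genes near regions. Odds ratios are given with 95% intervals because many p-values are below the smallest number the software stores. Neighbouring regions are not independent, so the intervals are too narrow. Gene positions came from a GRCm38 annotation, the same assembly as mm10. It matched 15489 of the tested genes, 99.3%, of which 13948 by symbol and 1541 by synonym, and a gene is near a region that lies within its body or 10 kb on either side.

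The alternatives tried cover pseudocounts, filters, scalings, the spread model, libraries in the fit, a replicate block, leaving out each library, minimum differences, overlap rules, equal peak numbers, region lengths, chromosomes and distances to genes. Motif searches were not run because no genome sequence was held. A DMR difference of at least 0.5 was not run because no methylation levels were held. The self-tests, draws and shifts used fixed seeds.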

Results

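Nuclear RNA was compared between excitatory, PV and VIP neurons of the adult mouse neocortex and between each of them and whole neocortex. Chromatin accessibility and DNA methylation were then compared between the 3 neuron types, and histone marks of excitatory neurons were set against both. RNA values are mean TPM ± SD with n = 2 libraries per group. Log2 differences are on the log2(TPM + 1) scale, and adjusted p-values come from limma over 15601 genes unless a list test is named.

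The genes whose promoters drove Cre recombinase were read first, as a check of the labels. Camk2a, a kinase of excitatory synapses, stood at 1214 and 1223 TPM in the excitatory libraries. It stood at 342 and 510 TPM in PV, 616 and 540 in VIP, and 504 and 513 in neocortex libraries. Pvalb, a calcium-binding protein of fast-spiking interneurons, stood at 209 and 277 TPM in PV libraries. Its values were 7.39 and 2.02 TPM in excitatory, 24.4 and 14.7 in VIP, and 126 and 112 in neocortex libraries. Vip, the peptide that names the third type, stood at 3139 and 2832 TPM in VIP libraries. Elsewhere it stood at 2.37 and 2.51 TPM in excitatory, 2.61 and 4.76 in PV, and 94.4 and 83.7 in neocortex libraries. Because nuclei were chosen by these genes, their differences are no finding. They are members of 4 lists (Camk2a of excitatory identity, Pvalb of the PV list, Vip of the VIP and neuropeptide lists), whose counts below include them, and without them camera lost 1 of 17 calls of these lists. Libraries of a group correlated at 0.987 to 0.993 across genes, and libraries of different groups at 0.921 to 0.957.

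**Figure D1:**
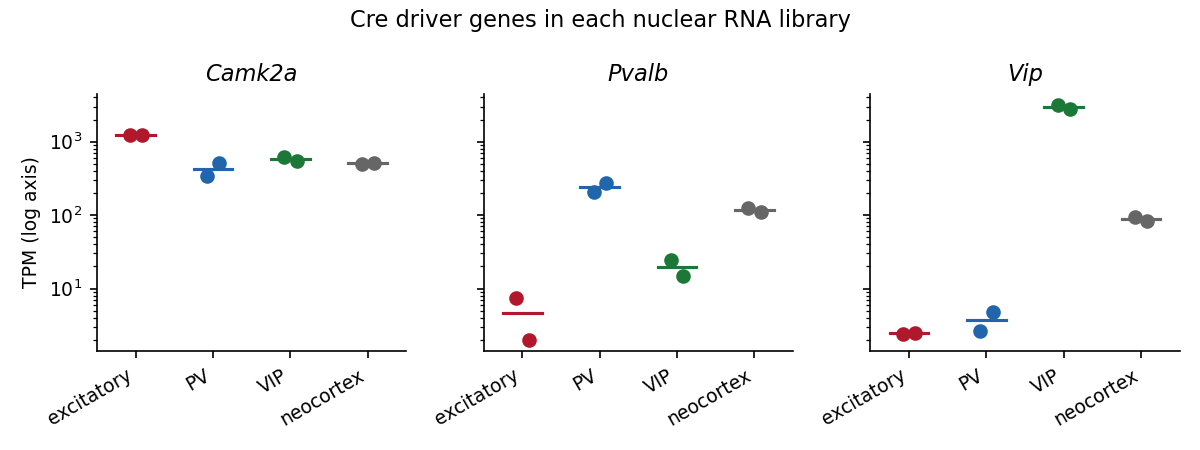
TPM of Camk2a, Pvalb and Vip in each RNA library on a log axis, with points for libraries and lines for group means. Each gene has its highest 2 libraries in the neuron type whose Cre driver it names, with Vip at 3139 and 2832 TPM in VIP libraries.

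PV nuclei differed from excitatory nuclei first in genes of interneurons. Erbb4, a neuregulin receptor of interneurons, rose by 6.38 on the log2 scale, from 6.43 ± 2.28 to 602 ± 19.7 TPM (adjusted p = 2.43e-07). Nxph1, a ligand of neurexins, rose by 6.14, and Adamtsl5, a secreted protein of the extracellular matrix, by 6.03. Btbd11 rose from 2.75 ± 0.0990 to 193 ± 0.884 TPM, a log2 difference of 5.69. Among genes lower in PV nuclei, Igfn1 stood at 67.9 ± 1.80 TPM in excitatory and 1.23 ± 0.0566 TPM in PV nuclei (log2 difference −4.95, adjusted p = 6.2e-07). Fxyd5, a regulator of the sodium pump, fell by 4.68, the potassium channel gene Kcnh4 by 4.58 and Otof, a calcium sensor of exocytosis, by 4.55. The collagen gene Col6a2 differed by −4.35 and Nxf7, of the nuclear RNA export family, by −4.25.

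Of 13 tested GABAergic identity genes, 12 were higher in PV than in excitatory nuclei. Gad1, which makes GABA, stood at 18.7 ± 0.0849 TPM in excitatory and 625 ± 46.9 TPM in PV nuclei. Slc32a1, the vesicular GABA transporter, rose by 5.54 and the homeobox gene Dlx1 by 5.09. Nrxn3, a neurexin, was the member that did not pass, at 473 and 461 TPM. The list's camera adjusted p was 3.23e-13, and the adjusted p = 0.201 with an estimated correlation. Of 17 genes of PV cells and their origin in the medial ganglionic eminence, 14 rose, among them the transcription factor gene Lhx6 by 4.93 and the neuropeptide gene Tac1 by 5.13. Without Pvalb 13 of 16 rose. This list's camera adjusted p was 1.66e-12, with an adjusted p = 0.201 with an estimated correlation. Of 18 excitatory identity genes, 15 fell, such as the vesicular glutamate transporter gene Slc17a7 (1012 ± 191 against 108 ± 46.3 TPM, log2 difference −3.27) and the transcription factor gene Neurod1 (−3.54). Cux2, Bcl11b and Nrgn were not called, at 116, 27.2 and 332 TPM in PV against 112, 15.1 and 441 TPM in excitatory nuclei. The camera adjusted p was 6.7e-08, and the adjusted p = 0.469 with an estimated correlation.

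Ion channel and neuropeptide genes were called in both directions between PV and excitatory nuclei, and camera called none of these lists. Of 25 voltage-gated potassium channel genes, 6 were higher and 10 lower in PV nuclei (camera adjusted p = 0.142; 0.024 without PV replicate 2). Kcnc1, which lets axons fire fast, stood at 1147 ± 7.81 TPM in PV and 100 ± 2.01 TPM in excitatory nuclei. Kcnv1, a modulatory subunit, was 130 ± 10.7 TPM in excitatory and 6.28 ± 2.57 TPM in PV nuclei. Of 21 sodium and calcium channel genes, 3 were higher and 8 lower (camera adjusted p = 0.296; fry adjusted p = 0.0115). The calcium channel subunit gene Cacna2d2 rose by 5.34 while its relatives Cacna2d1 and Cacna2d3 fell by 3.99 and 2.88. Of 15 neuropeptide genes, 4 were higher and 5 lower, and their median of −0.32 and mean of 0.15 had opposite signs (camera adjusted p = 0.952). Cort rose by 2.60, Npy by 2.22 and Tac1 by 5.13, and Adcyap1 fell by 2.31.

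Of 14 activity-regulated genes, 11 were lower in PV than in excitatory nuclei. Bdnf, a neurotrophin, was 23.1 ± 2.24 TPM in excitatory and 2.14 ± 0.382 TPM in PV nuclei, and Arc, of the postsynapse, 339 ± 6.23 and 63.0 ± 32.7 TPM. Egr3 fell by 2.79 and Npas4 by 2.40. The camera adjusted p was 1.43e-05, and the adjusted p = 0.589 with an estimated correlation. Of 17 VIP and caudal ganglionic eminence genes, 1 rose, Npas3 by 1.72, and 4 fell, among them the cannabinoid receptor gene Cnr1 by 1.98. Camera gave an adjusted p = 0.506, and the list's median of −0.09 was 0.04 under quantile normalization. Cck, also lower, moved from −2.05 to −1.35 on the log2 scale without PV replicate 1. Of 9 somatostatin and neurogliaform genes, 3 rose, with Crhbp, which binds corticotropin-releasing hormone, up by 4.29 (camera adjusted p = 0.218; fry adjusted p = 0.0327). Lists of other cells of the tissue held 1 higher and 2 lower genes of 12 for astrocytes, 1 higher of 12 for oligodendrocytes, 1 lower of 7 for their precursors, 1 lower of 11 for microglia and 0 of 9 for vascular cells. By limma the vascular genes had 0 calls also when adjusted over the list alone and 0 at an unadjusted p under 0.05, and their median of 0.04 and mean of −0.04 had opposite signs. The oligodendrocyte call, Cldn11, was lost without PV replicate 2, where it was 0.56, and without excitatory replicate 1 (0.93) or 2 (1.1). The precursor call, Matn4, was lost without excitatory replicate 1, where it was −0.56, and without PV replicate 1 (−1.83) or 2 (−1.3). Both calls were also lost when adjusted over the list alone. The astrocyte list had a camera adjusted p = 0.0942, and 0.00894 without PV replicate 2. Slc1a2, the main glutamate transporter of astrocytes, fell by 2.63 and Aif1 of microglia by 2.11. Of 20 cytosolic ribosomal protein genes limma called 0, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.214).

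Over all lists and contrasts, the numbers of called members were the same in 127 of 132 cases when adjusted over the list alone, and the other 5 are given where they arise. In all, 1313 genes were called higher and 1601 lower in PV than in excitatory nuclei. The PV libraries differed in respect of these groups: in PV replicate 2, excitatory identity genes lay a median of 0.76 above replicate 1 on the log2 scale, activity-regulated genes 0.77, neuropeptide genes 0.73 and oligodendrocyte genes 0.90. Without PV replicate 2 the counts were 1291 higher and 1742 lower.

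Tac2, Npas1 and Igf1 were among the genes with the largest differences between VIP and excitatory nuclei. Tac2, which encodes neurokinin B, was 2335 ± 57.9 TPM in VIP and 6.96 ± 5.31 TPM in excitatory nuclei (log2 difference 8.38, adjusted p = 7.12e-06). The transcription factor gene Npas1 rose by 7.48 to 480 ± 59.2 TPM and Igf1, a growth factor, by 7.43 to 727 ± 14.8 TPM. Htr3a, the ionotropic serotonin receptor, stood at 267 ± 65.8 TPM in VIP against 0.780 ± 0.707 TPM in excitatory nuclei. Dlx1 was 593 ± 58.7 against 3.10 ± 0.0566 TPM. Lower in VIP nuclei were Igfn1 (log2 difference −4.81), the sodium and calcium exchanger gene Slc24a4 (−4.67), the collagen gene Col6a1 (−4.65) and Robo3, a receptor of axon guidance (−4.56). Vwa3a fell by 4.33 and Adam33, a membrane protease, by 4.29.

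All 13 tested GABAergic identity genes were higher in VIP than in excitatory nuclei, with Dlx6 up by 6.90 and Erbb4 by 6.16 (camera adjusted p = 3.53e-16; adjusted p = 0.201 with an estimated correlation). Of 17 VIP and caudal ganglionic eminence genes, 15 were higher, and 14 of 16 without Vip (camera adjusted p = 1.05e-15; adjusted p = 0.221 with an estimated correlation). Prox1, a transcription factor of that origin, stood at 304 ± 28.8 TPM in VIP and 2.69 ± 1.71 TPM in excitatory nuclei. Calb2, which encodes calretinin, was 70.2 ± 7.23 TPM in VIP nuclei and listed at 0 in both excitatory libraries. All 18 excitatory identity genes fell, with Sv2b, a synaptic vesicle protein, down by 4.21 and the homeobox gene Emx1 by 3.95 (camera adjusted p = 5.82e-12; adjusted p = 0.415 with an estimated correlation). Camk2a, also lower by 1.08, kept a difference of −0.98 without VIP replicate 2 and then lost its call. Of 17 PV and medial ganglionic eminence genes, 3 were higher and 2 lower (camera adjusted p = 0.485). Kcnc1 and Cox6a2 were higher by 1.98 and 2.07. Pvalb was higher by 1.99, and by 1.25 without excitatory replicate 2.

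Of 25 potassium channel genes, 10 were lower and 1, Kcnc1, higher in VIP than in excitatory nuclei (camera adjusted p = 0.00986; adjusted p = 0.796 with an estimated correlation). Kcnh5 fell by 3.74 and Kcnv1 by 4.05. Of 21 sodium and calcium channel genes, 6 were lower and 1 higher, with the sodium channel subunit gene Scn4b at 2.08 ± 0.276 TPM in VIP against 18.4 ± 2.20 TPM in excitatory nuclei (camera adjusted p = 0.018; adjusted p = 0.552 with an estimated correlation). Of 14 GABA receptor genes, 5 fell, among them Gabra5 by 1.90 and Gabrd by 1.52 (camera adjusted p = 0.0122; adjusted p = 0.785 with an estimated correlation). Activity-regulated genes had 1 higher and 6 lower members of 14, with Arc down by 3.37 and Bdnf by 3.36 (camera adjusted p = 0.0319; adjusted p = 0.796 with an estimated correlation). Of 20 cytosolic ribosomal protein genes, 5 rose, such as Rpl8 by 1.29 (camera adjusted p = 4.63e-05; adjusted p = 0.696 with an estimated correlation). Of 15 neuropeptide genes, 6 rose and 3 fell, with Crh up by 6.98, and their median of −0.22 and mean of 1.85 had opposite signs (camera adjusted p = 0.107; fry adjusted p = 0.00495). Somatostatin and neurogliaform genes held 3 higher and 2 lower of 9 (camera adjusted p = 0.375; fry adjusted p = 0.0368), with a median of −0.08, a mean of 0.89 and a median of 0.04 under quantile normalization. Npy rose by 4.47 and Calb1 fell by 2.12. Of the glial lists, 2 of 12 astrocyte genes were lower, 3 of 12 oligodendrocyte genes higher, 2 of 7 precursor genes higher and 1 lower, and of 11 microglia and 9 vascular genes limma called 0, also when adjusted over the list alone, with 1 in each at an unadjusted p under 0.05. Cldn11, of myelin, was higher by 1.45 and Slc1a2 lower by 1.15. The calls of Mag, Mog and C1ql1 were lost without VIP replicate 1, at 1.03, 0.97 and 0.82, that of Pdgfra without VIP replicate 2, at 1.00, and that of Matn4 also without VIP replicate 1, at −1.49. Without excitatory replicate 1, the calls of Mag, C1ql1 and Matn4 were lost as well, at 1.045, 1.116 and −0.595. C1ql1 also lost its call without excitatory replicate 2, at 1.354, and Matn4 without VIP replicate 2, at −1.715. In all, 1341 genes were called higher and 1624 lower in VIP than in excitatory nuclei.

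**Figure D2:**
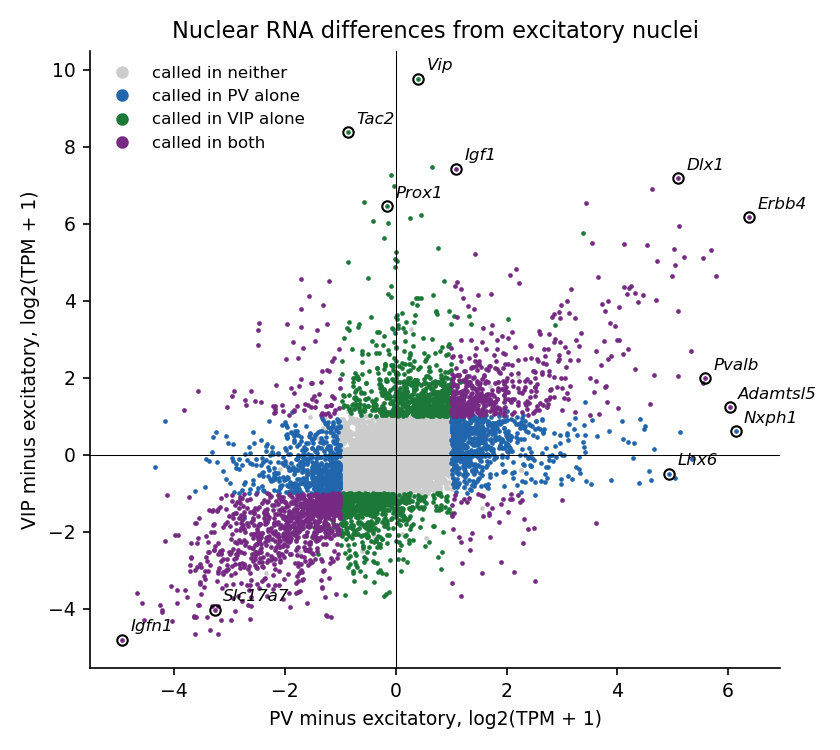
Log2 difference of PV minus excitatory nuclei (x axis) against VIP minus excitatory nuclei (y axis) for 15601 genes, coloured by call, with named genes circled. Erbb4 lies high on both axes at 6.38 and 6.16, Vip high on the VIP axis at 9.76, and Igfn1 low on both at −4.95 and −4.81.

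Compared with each other, PV and VIP nuclei differed in genes of the PV and VIP lists, which mix cell markers with genes of embryonic origin. Lhx6, a transcription factor of the medial ganglionic eminence, was 196 ± 14.1 TPM in PV and 3.62 ± 0.997 TPM in VIP nuclei (log2 difference 5.43, adjusted p = 5.35e-07). Sox6, of the same origin, was higher by 5.00 and Syt2, a calcium sensor of fast release, by 4.55. Lass1, a ceramide synthase that shares a transcript with Gdf1, differed by 5.80, Mypn by 5.66, Nxph1 by 5.53, Cacna2d2 by 5.45 and Eya4, a transcription cofactor, by 5.25. Higher in VIP nuclei were Tac2 (log2 difference −9.25), Htr3a (−7.35) and Adarb2, an RNA-editing family member, at 562 ± 124 TPM in VIP nuclei (−7.14). The stress peptide gene Crh differed by −7.02 and Npas1 by −6.83. Of the PV list, 15 of 17 genes were higher in PV nuclei, and 14 of 16 without Pvalb (camera adjusted p = 6.53e-14; adjusted p = 0.201 with an estimated correlation). Of the VIP list, 17 of 17 were lower in PV nuclei, and 16 of 16 without Vip (camera adjusted p = 3.92e-19; adjusted p = 0.201 with an estimated correlation).

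Of 18 excitatory identity genes, 5 were higher in PV than in VIP nuclei, such as Cux2 by 2.33 and Bcl11b by 2.19 (camera adjusted p = 0.0146; adjusted p = 0.796 with an estimated correlation; fry adjusted p = 0.0705). The list lay a median of 0.76 higher in PV replicate 2 than in replicate 1, and without PV replicate 2 its call was lost (camera adjusted p = 0.333), with 4 genes higher and a median of 0.31, while Cux2 stood at 2.46 and Bcl11b at 2.09. GABAergic identity genes had 2 higher and 5 lower members (camera adjusted p = 0.229; fry adjusted p = 0.00599), with Dlx6 lower by 2.27 in PV nuclei. Potassium channel genes had 10 higher and 5 lower members (camera adjusted p = 0.136; fry adjusted p = 0.043), with Kcna1 higher by 2.39 and Kcnd3 lower by 3.17. Sodium and calcium channel genes had 8 higher and 7 lower (camera adjusted p = 0.885), with Scn4b higher by 3.43 and the T-type calcium channel gene Cacna1g lower by 2.85. Somatostatin and neurogliaform genes had 3 higher and 3 lower members, and 4 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.959). Elfn1, a synaptic organizer, was lower by 3.69. Neuropeptide genes had 4 higher and 6 lower, and 5 higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.126, and 0.024 without PV replicate 2; fry adjusted p = 0.00471), with Penk, the enkephalin precursor, lower by 6.27. Of 14 activity-regulated genes, 5 were lower and 1 higher in PV nuclei, with Npas4 at −2.21 and Fos at −2.01 (camera adjusted p = 0.0467; adjusted p = 0.796 with an estimated correlation; fry adjusted p = 0.122). Of 20 ribosomal protein genes, 1 was lower (camera adjusted p = 0.000914; adjusted p = 0.785 with an estimated correlation; fry adjusted p = 0.0818). The lists of other cells held few calls: 1 higher and 1 lower of astrocytes, 0 of oligodendrocytes, 1 lower of their precursors, 1 lower of microglia and 0 of vascular cells, with the same counts when adjusted over the list alone. At an unadjusted p under 0.05, limma gave 3 oligodendrocyte genes and 1 vascular gene. Without PV replicate 2, limma called 4 oligodendrocyte, 2 precursor and 5 microglia genes, all lower in PV nuclei (camera adjusted p = 0.00152, 0.0362 and 0.0479). In all, 1192 genes were called higher and 1146 lower in PV than in VIP nuclei, and 1193 and 1291 without PV replicate 2.

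Each type had genes higher than in both others: 905 for excitatory, 530 for PV and 536 for VIP nuclei. Slc17a7 and Sv2b are among the first, Lhx6, Nxph1 and Cacna2d2 among the second, and Tac2 and Htr3a among the third. Higher in both PV and VIP than in excitatory nuclei were 506 genes, among them Erbb4 and Dlx1. This count did not use the contrast of PV with VIP, so it can hold genes of the PV and VIP counts just given. Independent lists would give 166.7, 100.3, 98.5 and 112.9 genes, and 100 simulations of unchanged groups gave at most 1. Neither is a strict reference, because contrasts that share a group are not independent and unchanged groups hold almost no calls to overlap. An excess over them would arise wherever the types differ, and does not show that PV and VIP share changes. Part of the excess may come from the libraries that the contrasts share. The differences of PV and of VIP from excitatory nuclei correlated at 0.563 across genes, where unchanged groups gave 0.501, and genes are not independent replicates. Their covariance was 0.521 against 0.0312 in unchanged groups, a difference of 0.489. Both contrasts subtract the same excitatory values, so a covariance above that of unchanged groups would arise wherever excitatory nuclei differ. It is no measure of changes shared by PV and VIP.

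Against whole neocortex, excitatory nuclei were lower in genes of interneurons and of glia. Cldn11, a junction protein of myelin, was 191 ± 41.6 TPM in neocortex and 3.73 ± 0.389 TPM in excitatory nuclei (log2 difference −5.33, adjusted p = 1.5e-05). Tyrobp, a signalling adaptor of microglia, fell by 5.39. Beta-s, a hemoglobin chain of blood, fell by 7.36 from 889 ± 883 TPM, with neocortex libraries far apart, and Hbb-b1 was listed at 0 in both excitatory libraries against 229 ± 258 TPM. Hsd3b4, of steroid metabolism, stood at 54.1 ± 5.67 TPM in excitatory nuclei and 5.36 ± 0.523 TPM in neocortex, and Lass1 was higher by 3.17. Krt20, a keratin, was higher by 3.65, and by 1.91 without neocortex replicate 1. Pcdha4-g, of the clustered protocadherins, was 12.4 ± 3.21 TPM and listed at 0 in both neocortex libraries. Of 12 oligodendrocyte genes, 12 fell (camera adjusted p = 8.38e-11; adjusted p = 0.415 with an estimated correlation), with Mag down by 5.18. Of 11 microglia genes, 10 fell (camera adjusted p = 8.03e-09; adjusted p = 0.415 with an estimated correlation), with the complement gene C1qb down by 4.27.

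Other glial lists and the interneuron lists were also lower in excitatory nuclei than in neocortex. Of 7 oligodendrocyte precursor genes, 5 fell, with the receptor gene Gpr17 down by 4.07 (camera adjusted p = 2.26e-05; adjusted p = 0.415 with an estimated correlation). Of 12 astrocyte genes, 5 fell, with the connexin gene Gja1 down by 2.62 (camera adjusted p = 0.000955; adjusted p = 0.469 with an estimated correlation). GABAergic identity genes had 1 higher and 11 lower members, with Slc32a1 down by 4.09 (camera adjusted p = 5.43e-10; adjusted p = 0.25 with an estimated correlation). The VIP list had 9 lower of 17, with Npas1 down by 3.41 (camera adjusted p = 2.67e-06; adjusted p = 0.415 with an estimated correlation). The PV list had 1 higher and 7 lower of 17, with Tac1 down by 3.98 (camera adjusted p = 0.00365; adjusted p = 0.415 with an estimated correlation). Of 9 somatostatin and neurogliaform genes, 5 fell, with Sst at 133 ± 66.8 against 838 ± 391 TPM (camera adjusted p = 0.00176; adjusted p = 0.517 with an estimated correlation). Neuropeptide genes had 11 lower of 15 (camera adjusted p = 2.95e-06; adjusted p = 0.415 with an estimated correlation). Of 20 ribosomal protein genes, whose mRNA sits mainly in the cytoplasm, 12 fell (camera adjusted p = 1.32e-10; adjusted p = 0.463 with an estimated correlation). Excitatory identity genes had 3 higher members of 18 (camera adjusted p = 0.499). Cux2 lost its call without excitatory replicate 1, at 0.94, and Rorb without excitatory replicate 2, at 0.88.

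Excitatory nuclei had 1770 genes higher and 1606 lower than neocortex as deposited, and 1211 higher and 1990 lower after median-of-ratios scaling. The median difference of all genes was 0.17 as deposited and 0.01 with that scaling. Relative to 0.17, the oligodendrocyte and microglia genes named above remain far below the median. For PV nuclei the counts were 2249 higher and 2213 lower as deposited, 1793 and 2532 with median-of-ratios scaling, and 2739 and 2503 without PV replicate 2. The median of all genes for PV moved from 0.12 to −0.01 under that scaling. For VIP nuclei 2026 genes were higher and 1736 lower.

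PV nuclei were lower than neocortex in myelin genes, with Opalin at 4.44 ± 3.64 against 135 ± 4.39 TPM (log2 difference −4.83, adjusted p = 8.6e-05) and the tetraspanin gene Cd9 at 2.25 ± 0.113 against 95.9 ± 9.48 TPM. Tac2 fell by 4.90 and Hbb-b1 by 5.80. Higher in PV nuclei were Lass1 by 5.69, Adamtsl5 by 4.49, Gm1604b by 4.47 and Mypn by 4.43. Of 17 PV list genes, 15 were higher, and 16 when adjusted over the list alone, with Syt2 up by 3.25 and the ankyrin gene Ank1 by 3.57 (camera adjusted p = 1.28e-07; adjusted p = 0.264 with an estimated correlation). GABAergic identity genes had 11 higher of 13, with Gad1 up by 2.45 (camera adjusted p = 3.19e-05; adjusted p = 0.415 with an estimated correlation). Excitatory identity genes had 1 higher and 15 lower of 18, with Neurod6 down by 2.89 (camera adjusted p = 3.28e-06; adjusted p = 0.552 with an estimated correlation). The VIP list had 11 lower of 17 (camera adjusted p = 2.3e-06; adjusted p = 0.415 with an estimated correlation). All 12 oligodendrocyte genes fell (camera adjusted p = 8.3e-09), as did all 7 precursor genes (4.92e-05), 10 of 11 microglia genes (7.52e-08), and 9 of 12 astrocyte genes, with 1 higher (8.32e-05), each with an adjusted p = 0.415 with an estimated correlation. Activity-regulated genes had 12 lower of 14, with Bdnf down by 2.72 (camera adjusted p = 1.11e-05; adjusted p = 0.589 with an estimated correlation). Neuropeptide genes had 2 higher and 11 lower of 15 (camera adjusted p = 0.000418; adjusted p = 0.517 with an estimated correlation). Ribosomal protein genes had 12 lower of 20 (camera adjusted p = 1.18e-07; adjusted p = 0.552 with an estimated correlation). In PV replicate 2 the genes called lower than neocortex lay a median of 0.37 above replicate 1, and excitatory identity genes 0.76.

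VIP nuclei were higher than neocortex in interneuron genes, with Adarb2 up by 5.31, Dlx6 at 332 ± 35.1 against 8.82 ± 0.495 TPM, and Igf1 up by 5.44. They were lower in Tmem63a, a mechanically gated channel of the membrane, at 3.70 ± 2.16 against 81.5 ± 14.7 TPM, in Srp54c by 4.72 and in Col6a1 by 4.05. Ccl21b, a chemokine, was listed at 0 in both VIP libraries against 25.4 ± 11.0 TPM. Of 17 VIP list genes, 15 were higher, with Chat, which makes acetylcholine, up by 5.00 (camera adjusted p = 2.19e-10; adjusted p = 0.289 with an estimated correlation). GABAergic identity genes had 12 higher of 13 (camera adjusted p = 5.5e-09; adjusted p = 0.264 with an estimated correlation). Excitatory identity genes had 17 lower of 18, with Fezf2 down by 3.62 (camera adjusted p = 1.17e-10; adjusted p = 0.415 with an estimated correlation). The PV list had 2 higher and 8 lower of 17 (camera adjusted p = 0.0467; adjusted p = 0.589 with an estimated correlation), and without Pvalb its call was lost (camera adjusted p = 0.0884), with 2 higher and 7 lower. Oligodendrocyte genes had 11 lower of 12 (camera adjusted p = 9.04e-09), precursor genes 6 of 7 (0.000303), microglia genes 10 of 11 (1.07e-07) and astrocyte genes 9 of 12 (9.09e-05), each with an adjusted p = 0.415 with an estimated correlation. Vascular genes had 3 lower of 9, with the vitronectin gene Vtn down by 1.83 (camera adjusted p = 0.142; fry adjusted p = 0.0411). Activity-regulated genes had 6 lower of 14 (camera adjusted p = 0.03; adjusted p = 0.796 with an estimated correlation), GABA receptor genes 1 higher and 4 lower of 14 (camera adjusted p = 0.0181; adjusted p = 0.785 with an estimated correlation) and ribosomal protein genes 3 lower of 20 (camera adjusted p = 0.000153; adjusted p = 0.759 with an estimated correlation).

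Open chromatin, read as ATAC-seq peaks, was partly shared between neuron types, and each pair shared more than shifted lists did. The lists held 162327 peaks for excitatory, 103361 for PV and 97628 for VIP neurons, covering 114.5, 74.23 and 66.39 Mb. Of excitatory peaks, 41.0% overlapped a PV peak and 33.0% a VIP peak, where shifted lists gave 5.81% and 5.31%. Of PV peaks, 64.5% overlapped an excitatory and 52.4% a VIP peak, and of VIP peaks 55.3% overlapped an excitatory and 55.9% a PV peak, where shifts gave 9.07%, 5.40%, 8.76% and 5.71%. The share of covered bases in common was 0.355 for PV and VIP, 0.317 for excitatory and PV, and 0.245 for excitatory and VIP. Found in 1 type alone were 84988 excitatory peaks (52.4%, 95% interval 52.1 to 52.6), 25195 PV peaks (24.4%, 24.1 to 24.6) and 32101 VIP peaks (32.9%, 32.6 to 33.2). Merged over the types, 42037 of 229274 regions (18.3%) were open in all 3. The lists differ in length, and with the 97628 widest peaks of each the shares alone were 45.3%, 30.8% and 38.4%. Peaks found alone were narrower than shared ones, with medians of 524 and 638 bp in excitatory neurons, so this choice by width bears on the shares. The region lists give no depth, so a peak missing from a list was not detected there, which is not the same as closed.

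Unmethylated regions were largely shared between the neuron types, and low-methylated regions partly. UMRs, which often lie at promoters, numbered 19724 in excitatory, 17866 in PV and 17316 in VIP neurons. LMRs, often at distal enhancers, numbered 115849, 79728 and 77731, with median lengths of 611, 573.5 and 538 bp. Of merged UMRs, 72.4% were found in all 3 types, and of merged LMRs, 15.8%. UMRs found in 1 type alone numbered 2798 in excitatory neurons (14.2%, 95% interval 13.7 to 14.7), 1001 in PV (5.27 to 5.95%) and 716 in VIP neurons (4.13%, 3.84 to 4.44). With equal numbers of the longest UMRs, an alternative chosen after seeing the data, the shares were 13.9%, 6.23% and 7.01%, which turns the order of PV and VIP. Among UMRs of at least the median length the shares were 23.4%, 13.0% and 11.5%. LMRs found in 1 type alone made up 49.7%, 28.7% (28.4 to 29.0) and 34.2% (33.9 to 34.6), and with equal numbers of the longest LMRs 45.2%, 34.2% and 40.5%.

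The DMR table held 251301 regions of median length 275 bp, covering 85.32 Mb, with 30 of 32 possible codes. A single position was set in 170575 of them (67.9%). Position 2 alone was set in 72474 DMRs (28.8%), position 3 in 39123 (15.6%), position 4 in 28003 (11.1%), position 5 in 26835 (10.7%) and position 1 in 4140 (1.65%). Positions 2 and 3 together were set in 20669 (8.22%), 2 and 4 in 6038 (2.40%) and 3 and 4 in 5677 (2.26%), and no position in 13348 (5.31%).

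Each of positions 2, 3 and 4, whose meaning the file does not state, went with open chromatin of 1 neuron type. DMRs of position 2 alone overlapped excitatory ATAC-seq peaks in 58.0% of cases, against 12.5% of the DMRs with another single position (odds ratio 9.68, 95% interval 9.45 to 9.92). They overlapped PV and VIP peaks in 11.2% and 6.98%. DMRs of position 3 overlapped PV peaks in 43.7% against 9.97% (odds ratio 7.00, 6.81 to 7.19), and excitatory and VIP peaks in 16.6% and 11.9%. DMRs of position 4 overlapped VIP peaks in 51.7% against 8.82% (odds ratio 11.1, 10.8 to 11.4), and excitatory and PV peaks in 11.3% and 10.4%. Positions 1 and 5 overlapped peaks of any type in 5.75% to 9.37%, where shifted lists gave 3.77% to 6.58% over all positions. LMRs gave the same pairing, with odds ratios of 9.46 (9.25 to 9.68) for position 2 in excitatory, 18.0 (17.5 to 18.5) for position 3 in PV and 15.4 (15.0 to 15.9) for position 4 in VIP LMRs. LMRs and DMRs both come from MethylC-seq, so this pairing is not independent of the DMR calls. DMRs with positions 2 and 3 set overlapped excitatory peaks in 57.0%, PV peaks in 44.0% and VIP peaks in 10.7%.

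**Figure D3:**
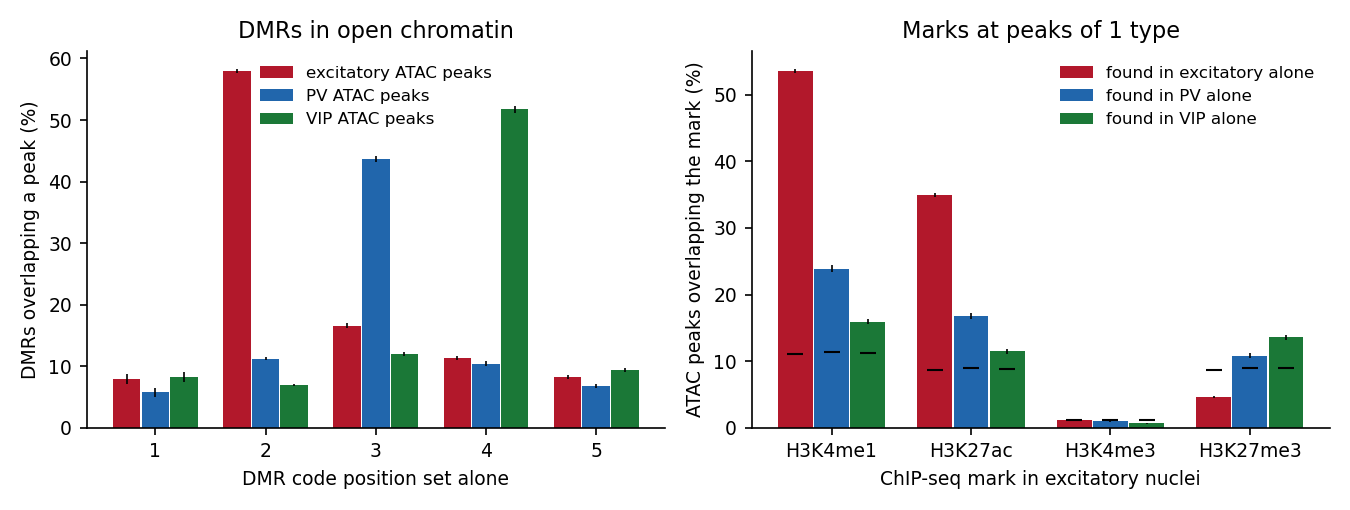
Left, percent of DMRs with 1 position set that overlap ATAC-seq peaks of each neuron type; right, percent of ATAC-seq peaks found in 1 type alone that overlap histone marks of excitatory neurons. Bars carry 95% exact intervals and dashes mark the mean of 200 shifts, with 58.0% for position 2 in excitatory peaks and 53.5% for H3K4me1 at excitatory peaks.

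Active histone marks of excitatory neurons lay at the open chromatin of excitatory neurons more often than at that of interneurons. H3K4me1, a mark of enhancers, overlapped 53.5% of peaks found in excitatory neurons alone, 23.9% of those in PV and 15.9% of those in VIP neurons alone, where shifts gave 11.1%, 11.3% and 11.3%. The odds ratio was 3.68 (95% interval 3.56 to 3.80) against PV and 6.08 (5.88 to 6.28) against VIP peaks. H3K27ac, a mark of active enhancers and promoters, overlapped 34.9%, 16.7% and 11.5% (8.70%, 8.91% and 8.89% in shifts), with odds ratios of 2.68 (2.58 to 2.77) and 4.15 (4.00 to 4.31). H3K27me3, the mark of Polycomb repression, ran the other way, with 4.58%, 10.8% and 13.6% (8.71%, 8.99% and 8.91% in shifts) and odds ratios of 0.395 (0.375 to 0.415) and 0.305 (0.291 to 0.319). H3K4me3, a mark of promoters, was rare at all of them, with 1.11%, 1.02% and 0.657%, at or under the highest of the shifts, and no difference was detected between excitatory and PV peaks (Fisher's exact test, adjusted p = 0.26). Over UMRs, H3K4me1 lay at 75.6%, 72.4% and 70.8%, H3K4me3 at 55.8%, 60.9% and 62.7% and H3K27me3 at 13.4%, 13.4% and 14.3%, where shifts gave 11.0%, 10.8% and 10.7% for the last. Over LMRs, H3K27ac lay at 47.9%, 39.5% and 32.8% and H3K27me3 at 8.51%, 9.99% and 13.0% (9.11%, 9.06% and 9.02% in shifts). DMRs of position 2 alone had H3K27ac in 46.2%, against 25.3% for position 3 and 14.6% for position 4, and H3K27me3 in 5.01%, 8.58% and 12.4%. These marks were measured in excitatory neurons alone, so a region of another type without a mark may carry it there.

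Genes near open chromatin of a type were more often higher in that type. Of 10760 genes near a peak found in excitatory neurons alone, 798 (7.42%) were higher in excitatory than in both other nuclei, against 102 of 4729 others (2.16%). The odds ratio was 3.63 (95% interval 2.94 to 4.46; Fisher's exact test, adjusted p = 2.15e-43). For PV it was 2.86 (2.38 to 3.43), with 345 of 6353 genes (5.43%) against 180 of 9136 (1.97%), and for VIP 2.99 (2.49 to 3.59), with 356 of 6369 (5.59%) against 177 of 9120 (1.94%). The share grew with the number of such peaks, to 13.3% of 2852 genes with 5 or more in excitatory, 9.58% of 898 in PV and 12.3% of 877 in VIP neurons. Near VIP peaks the share also grew for excitatory genes, from 4.92% with 0 peaks to 8.44% with 5 or more. For PV genes near VIP peaks it went from 2.99% to 5.47%. Near excitatory peaks, PV genes went from 3.55% to 3.93% and VIP genes from 3.66% to 3.89%. Like-type median log2 differences went from −0.09 to 0.29 in excitatory, −0.04 to 0.17 in PV and −0.03 to −0.02 in VIP neurons. These shares were not split by gene length. DMRs of a single position gave odds ratios of 3.48 (2.85 to 4.23) for position 2 with excitatory, 3.06 (2.50 to 3.71) for position 3 with PV and 3.36 (2.80 to 4.01) for position 4 with VIP genes. Some pairs of unlike type lay near 1, at 0.932 for PV genes near excitatory peaks (adjusted p = 0.512) and 0.979 for VIP genes near PV peaks (adjusted p = 0.823). Others did not, with excitatory genes near VIP peaks at 1.47 (adjusted p = 5.23e-08), PV genes near VIP peaks at 1.33 (0.002), excitatory genes near DMRs of position 4 at 1.44 (3.82e-07), and VIP genes near DMRs of position 3 at 0.685 (3.57e-05) and of position 2 at 0.804 (0.0263). DMRs of positions 1 and 5 gave 1.56 to 1.95 with genes of every type. Within 100 kb, the calls of PV genes near VIP peaks (1.31) and near position 1 (1.18) and of VIP genes near position 2 (0.843) were lost, and VIP genes near position 5 stood at 0.770 (adjusted p = 0.0565). Long genes hold more regions by chance, and the tests of like type held in each of 3 classes of gene length. Excitatory genes near VIP peaks gave 0.885, 1.16 and 1.31 from short to long genes (Fisher's exact test, adjusted p = 0.592, 0.364 and 0.0326). PV genes near VIP peaks gave 1.25, 1.29 and 1.27 (0.285, 0.215 and 0.232). With position 4, excitatory genes gave 0.851, 0.979 and 1.27 (0.555, 0.978 and 0.0395). VIP genes near position 3 kept their call in each class. Genes of every type near position 1 lost theirs among short genes. Among genes of middle length, excitatory and PV genes near position 1 also lost theirs, at 1.73 and 0.856 (0.0838 and 0.922). VIP genes near position 2 lost theirs among middle and long genes, at 0.728 and 0.760 (0.116 and 0.282). VIP genes near position 5 lost theirs among short genes, at 1.09 (0.607).

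**Figure D4:**
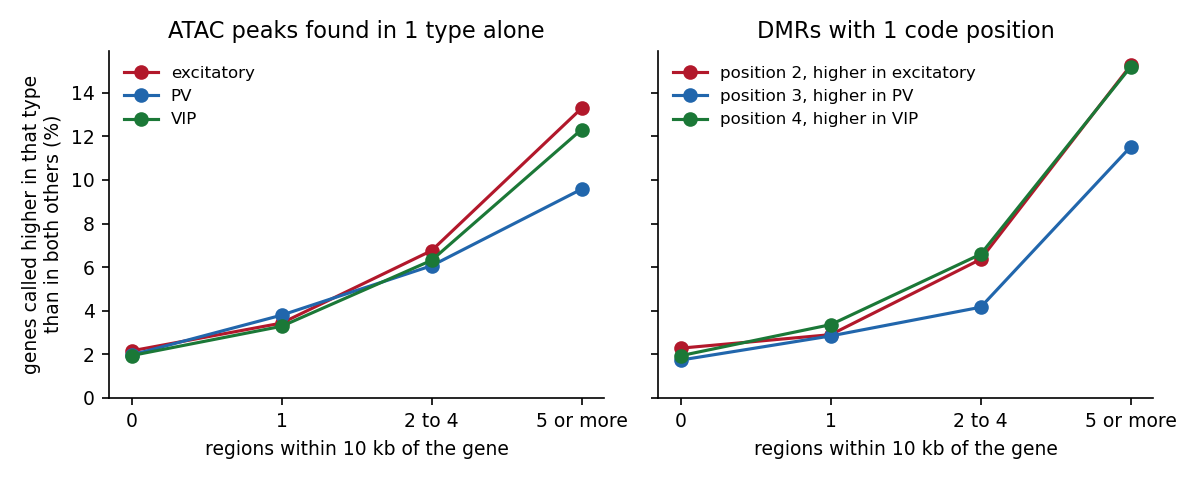
Percent of genes called higher in a neuron type by the number of nearby regions (0, 1, 2 to 4, 5 or more), for ATAC-seq peaks found in that type alone and for DMRs of 1 position. The share with 5 or more peaks was 13.3% in excitatory, 9.58% in PV and 12.3% in VIP neurons.

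At 8 loci read in full, peaks were counted within each gene and 10 kb on either side. Around Prox1 (mm10 chromosome 1, 190118035 to 190170827), VIP neurons had 18 ATAC-seq peaks, 17 of them in VIP alone, against 1 each in excitatory and PV neurons. Of its 33 DMRs, 30 had position 4 set. Around Lhx6 (chromosome 2, 36081950 to 36105992), PV neurons had 6 peaks, all in PV alone, against 1 in each other type, and 16 of 23 DMRs had position 3 alone. Pvalb (chromosome 15, 78191112 to 78206400) had 6 PV, 3 VIP and 1 excitatory peaks, and Vip (chromosome 10, 5639193 to 5647617) had 4 VIP, 1 PV and 2 excitatory peaks. Slc17a7 (chromosome 7, 45163921 to 45176139) had 7 excitatory peaks, 4 of them in excitatory alone, 3 PV and 3 VIP peaks, with 4 H3K27ac regions and 0 H3K27me3 regions. Neurod6 (chromosome 6, 55677818 to 55681263) had 5 excitatory, 2 PV and 1 VIP peaks. Gad1 (chromosome 2, 70561303 to 70602014) had 10 PV, 10 VIP and 3 excitatory peaks, with 0 H3K27ac and 3 H3K27me3 regions. Gad2 (chromosome 2, 22621015 to 22693877) had 9 PV, 10 VIP and 1 excitatory peaks, with 5 H3K27me3 regions.

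**Figure D5:**
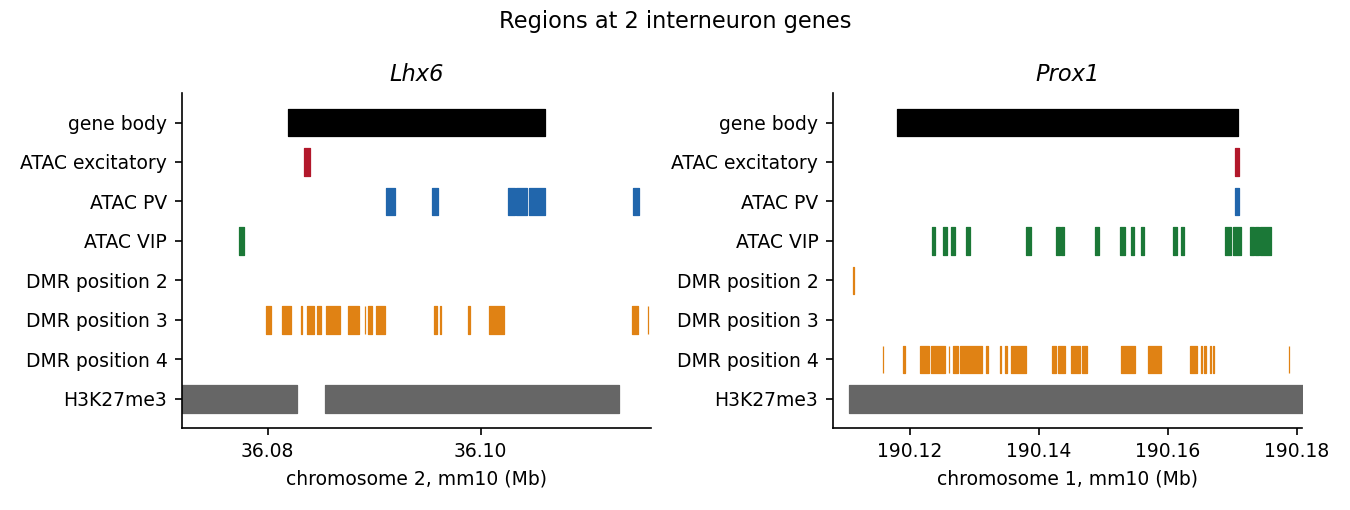
Maps of Lhx6 on chromosome 2 and Prox1 on chromosome 1 (mm10 positions on the x axis), with the gene body, ATAC-seq peaks of the 3 types, DMRs of positions 2, 3 and 4 alone and H3K27me3 regions of excitatory neurons. PV has 6 peaks at Lhx6 and VIP 18 peaks at Prox1, where the other types have 1 each.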

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

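Of the tests in this part, those of the PV libraries and of peak list length were chosen only after the result was seen.

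Genes of other cells lay higher in PV replicate 2 than in PV replicate 1: excitatory identity genes by a median log2 difference of 0.76 (17 of 18 genes), oligodendrocyte genes by 0.90 (12 of 12) and microglia genes by 0.75 (10 of 11). RNA from other cells of the neocortex in replicate 2 may account for this. The 2213 genes called lower in PV nuclei than in neocortex differed by 0.366, against −0.013 for genes not called, and 6 lists of other cells were higher. These lists include the excitatory identity, oligodendrocyte and microglia lists just named, and the 2213 genes hold members of them. Both values therefore largely restate the pattern. The share of neocortex RNA needed had a median of 12.1% by excitatory identity genes (4.26 to 38.6) and of 3.73% by microglia genes (−17.5 to 9.75), so an even mix was not shown. Vascular genes were not higher, with a median of −0.09 and 4 of 9 genes up, and in excitatory, VIP and neocortex libraries the 2213 genes differed by −0.06, −0.01 and 0.02. Single lists also differed between replicates of those groups. In the same order, oligodendrocyte genes differed by 0.16, −0.28 and 0.42, microglia genes by 0.38, −0.14 and −0.13 and excitatory identity genes by −0.03, −0.19 and 0.06. Cytoplasmic RNA carried with the nuclei cannot be told apart from this, because ribosomal protein genes also rose, by 0.382 in 19 of 20 genes, less than excitatory identity genes but not near 0. INTACT capture should remove untagged nuclei, and no biological explanation was tested, because the labels give no difference between replicates.

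H3K27me3 of excitatory neurons covered 147 of 502 genes that were higher in both PV and VIP than in excitatory nuclei (29.3%, 95% interval 25.3 to 33.5), against 11.8% of genes called in neither contrast. Gene length is argued against as the whole cause, because 1000 draws matched on length had a median of 11.753% and a highest value of 16.7%. Low expression in excitatory nuclei could carry part of the difference or more. Draws matched on 10 classes of excitatory TPM had a median of 20.518% and a highest value of 25.7%, below 29.3% but inside its interval. Genes can still differ in TPM within a class, so the test does not settle this cause. Draws matched on both reached 27.9%. A candidate explanation that stays open is Polycomb repression, in excitatory neurons, of genes of other neuron types, a hypothesis found on the same data that needs H3K27me3 of PV or VIP nuclei, which the series does not hold.

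Excitatory and PV neurons alone shared 23204 merged ATAC-seq regions, against 11224 for PV and VIP and 10525 for excitatory and VIP. The longer excitatory list may account for the excess over PV and VIP, because with equal numbers of the widest peaks the counts were 14547 and 20499, a choice by width that could itself favour shared peaks. A longer list in PV than in VIP neurons is argued against for the excess over excitatory and VIP, where equal numbers left 6899. Excitatory nuclei among the PV nuclei would predict more overlaps with DMRs of position 2 alone than with DMRs of positions 2 and 3. This holds only if positions 2 and 3 stand for excitatory and PV neurons, which the file does not state. Of the 23204 regions, 4780 overlapped a DMR of position 2 alone and 5450 one of positions 2 and 3, or 53.275% (52.3 to 54.2) of these overlaps. The test cannot decide, because a region can count in both and many regions had neither DMR. That source therefore stays open, and a likeness of the types themselves was not tested.

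Against neocortex, 195 genes were called in opposite directions in PV and VIP nuclei with their difference also called by limma, 84 higher in PV, such as Lhx6 and Cacna2d2, and 111 higher in VIP, such as Tac2 and Htr3a. Between excitatory and PV nuclei 201 genes were so called, 101 higher in excitatory, such as Igfn1 and Otof, and 100 higher in PV, such as Erbb4 and Nxph1. Between excitatory and VIP nuclei the number was 209, with 103 higher in excitatory, such as Slc24a4 and Robo3, and 106 higher in VIP, such as Npas1 and Igf1. The spike-in sequences, which no comparison uses, summed to between 2754 and 17656.8 TPM per library, with the lowest in excitatory replicate 2 and the highest in VIP replicate 1.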

How the results depend on the processing

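Of the tests in this part, those with equal numbers of the longest UMRs and LMRs and camera without PV replicate 2 or without the Cre driver genes were chosen only after the result was seen. Over 34 settings, 8321 alternative values were computed for 724 results. Of 479 for the main results, 394 were the same, 77 moved, 5 became weaker, 2 stronger and 1 reversed. A count moved if it changed by a factor above 1.5 and a share if it left its 95% interval. For single genes and lists 7461 were the same, 347 weaker and 34 stronger. The counts of genes follow the minimum difference and the pseudocount by construction, since both set which differences reach the minimum. Without a minimum difference, genes higher and lower numbered 2769 and 2898 for PV against excitatory, 2618 and 3223 for VIP against excitatory, 2789 and 2244 for PV against VIP, 4638 and 2973 for excitatory, 4858 and 3717 for PV and 3927 and 3358 for VIP against neocortex, and 1712, 1278, 1107 and 1279 for excitatory, PV and VIP above both others and for PV and VIP above excitatory. With a log2 difference of at least 2 the same counts were 340 and 494, 342 and 475, 269 and 353, 92 and 429, 308 and 651, 340 and 523, and 235, 125, 157 and 102. With a pseudocount of 5, genes lower in PV than excitatory numbered 1016, higher and lower in VIP than excitatory 891 and 1055, in PV than VIP 754 and 722, in excitatory than neocortex 1015 and 1058, in PV than neocortex 1455 and 1399 and in VIP than neocortex 1260 and 1017, with 568 and 331 for excitatory and VIP above both others and 306 for PV and VIP above excitatory. Other settings kept the 16 counts between 0.684 and 1.24 times the main ones.

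Leaving out 1 library in turn gave ranges of 1206 to 1397 and 1527 to 1742 genes higher and lower in PV than excitatory, 1208 to 1433 and 1478 to 1590 in VIP than excitatory, 1096 to 1264 and 989 to 1291 in PV than VIP, 1299 to 1957 and 1423 to 1735 in excitatory than neocortex, 1784 to 2739 and 1872 to 2503 in PV than neocortex, and 1635 to 2076 and 1563 to 1648 in VIP than neocortex. For genes above both others the ranges were 823 to 923 in excitatory, 468 to 540 in PV and 454 to 572 in VIP, and 449 to 618 for PV and VIP above excitatory. A group left with 1 library is assumed to vary like the others. Camera without PV replicate 2 lost 1 of 20 calls, excitatory identity of PV against VIP (adjusted p = 0.333), and gained 8 of 66. Without the Cre driver genes camera lost 1 of 17 calls, the PV list of VIP against neocortex (adjusted p = 0.0884), and gained 0 of 24. Of 476 pairs of a named gene and a contrast, 37 lost their call without some library, 1 gained it and 0 reversed. Among those lost for PV against excitatory were Penk, Cldn11, Matn4 and Bmi1, for VIP against excitatory Camk2a, S100b, Mag, Mog, Matn4, C1ql1, Pdgfra, Tet3, Bmi1 and Rps9, for PV against VIP Gabbr2, Egr1, Ring1, Ezh2 and Gsx2, for excitatory against neocortex Cux2, Rorb, Ly6c1, Tek, Kcnh7, Kcna4, Gria3, Drd2 and Tet3, for PV against neocortex Sst, Ly6c1, Rgs5 and Gadd45a, and for VIP against neocortex Ly6c1, Slco1a4, Tet2 and Rps9. The labels give no sign that replicate numbers pair the samples, and deviations of same-numbered libraries correlated between −0.064 and 0.173 over 6 pairs of groups. A fit with a replicate block called 1313 and 1598 genes for PV against excitatory and gave the 16 counts at 0.992 to 1.00 times the main ones. Under the replicate block 50 of 51 camera calls held, and activity-regulated genes of PV against VIP had a camera adjusted p = 0.0523.

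ATAC-seq peaks found in 1 type alone made up 55.44%, 26.26% and 34.94% in excitatory, PV and VIP neurons with an overlap of 50%, and 45.31%, 30.75% and 38.38% with equal numbers of the widest peaks. On autosomes the excitatory share was 52.06%. With an overlap of 50% the UMR shares were 16.88%, 6.504% and 4.787% and the LMR shares 58.75%, 35.40% and 40.66%. With regions of at least the median length they were 23.44%, 13.03% and 11.49%, and 56.51%, 36.90% and 44.32%. With equal numbers of the longest regions the UMR shares were 13.92%, 6.225% and 7.005% and the LMR shares 45.15%, 34.22% and 40.49%. Among DMRs of at least the median length, 23.37% had position 2 alone, 13.41% position 3, 9.599% position 4, 10.28% position 5, 10.82% positions 2 and 3, 3.483% positions 2 and 4 and 3.179% positions 3 and 4. A stricter overlap raises shares found alone by construction, and for the other changes the cause was not tested. All tests of DMRs in ATAC-seq peaks and of histone marks kept their calls. The odds ratio of excitatory genes near PV peaks passed the threshold with the gene body alone (1.2032) and with a pseudocount of 0.1 (1.2252). Lost calls were PV genes near VIP peaks (1.3081) and near DMRs of position 1 (1.1765) within 100 kb, and VIP genes near DMRs of position 2 with the gene body alone (0.83636), within 100 kb (0.84338) and with a pseudocount of 0.1 (0.88098). Within 100 kb, VIP genes near DMRs of position 5 had an odds ratio of 0.77011 (adjusted p = 0.0565), the reverse of the main direction. For these odds ratios the cause was not tested. Depth is unknown for every file, which limits statements on genes listed at low TPM and on regions missing from a list.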

Other observations

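Of the tests in this part, those without PV replicate 2 were chosen only after the result was seen.

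Receptor genes were called in both directions between the neuron types. Of 22 glutamate receptor genes, 2 were higher and 6 lower in PV than in excitatory nuclei (camera adjusted p = 0.0794; fry adjusted p = 0.0114). The NMDA receptor gene Grin2d was 35.6 ± 3.57 TPM in PV, 34.6 TPM in VIP and 1.68 ± 0.403 TPM in excitatory nuclei (n = 2 each), and the kainate receptor gene Grik1 148 ± 13.9, 144 ± 9.70 and 18.0 ± 0.262 TPM. In VIP nuclei 4 were higher and 6 lower than in excitatory nuclei (camera adjusted p = 0.687), with the AMPA receptor gene Gria3 down by 2.70, and 4 were higher and 7 lower in PV than in VIP nuclei (camera adjusted p = 0.533), with the metabotropic gene Grm8 down by 3.83. Of 14 GABA receptor genes, 2 were higher and 3 lower in PV than in excitatory nuclei (camera adjusted p = 0.571). Gabrd, of receptors outside synapses, was 378 ± 29.8 TPM in PV, 118 ± 26.9 in excitatory and 40.2 ± 4.23 in VIP nuclei, and Gabra2 fell by 2.83 in PV nuclei. Of 24 neuromodulator receptor genes, 10 were higher and 9 lower in VIP than in excitatory nuclei (camera adjusted p = 0.637). The adrenergic receptor gene Adra1b rose by 3.29 and the muscarinic receptor gene Chrm2 fell by 3.56. In PV nuclei 2 were higher and 7 lower (camera adjusted p = 0.0936, and 0.0176 without PV replicate 2; fry adjusted p = 0.0387), with Oprd1, the delta opioid receptor, at 207 ± 25.7 TPM against 42.7 ± 3.86 TPM. Between PV and VIP nuclei 6 were higher and 12 lower in PV (camera adjusted p = 0.0951, and 0.024 without PV replicate 2; fry adjusted p = 0.0154). In neuropeptide, neuromodulator and GABA receptor genes, PV replicate 2 lay above replicate 1 by medians of 0.73, 0.27 and 0.44 on the log2 scale.

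Of 22 synaptic adhesion genes, 4 were higher and 6 lower in PV than in excitatory nuclei (camera adjusted p = 0.506), with Cntnap4 at 155 ± 18.6 against 17.3 ± 1.73 TPM. In VIP nuclei 3 were higher and 4 lower than in excitatory nuclei (camera adjusted p = 0.763). Excitatory nuclei had 7 higher than neocortex, such as Cntn5 by 1.44 (camera adjusted p = 0.00189; adjusted p = 0.506 with an estimated correlation). The sodium and calcium channel list also passed there, with 6 higher and 1 lower, Cacna1d being up by 1.35 and Cacna2d2 down by 1.53 (camera adjusted p = 0.035; adjusted p = 0.589 with an estimated correlation). Of 11 tested progenitor transcription factor genes, 2 were higher in PV and 3 in VIP than in excitatory nuclei (camera adjusted p = 0.72 and 0.137; fry adjusted p = 0.0108 for VIP). Sox2, a factor of neural stem cells, was 16.0 ± 1.69 TPM in PV, 28.7 ± 3.11 in VIP and 1.49 ± 1.20 in excitatory nuclei. For PV the list's median of −0.06 and mean of 0.39 had opposite signs, and the median was 0.02 under quantile normalization. Of 16 genes of the DNA methylation machinery, limma called 0 between PV and excitatory nuclei, with 7 at an unadjusted p under 0.05 (camera adjusted p = 0.931), and 1 higher and 2 lower in VIP than in excitatory nuclei (camera adjusted p = 0.765). Between PV and excitatory nuclei 7132 of all 15601 tested genes had such an unadjusted p. A call also needs a log2 difference of at least 1. Dnmt3a, a writer of methylation, stood at 158 TPM in excitatory, 121 in PV and 119 in VIP nuclei, and Tet2, an oxidase of it, at 152, 279 and 175 TPM. Of 17 Polycomb and H3K27 demethylase genes, 1 was higher and 2 lower in PV than in excitatory nuclei (camera adjusted p = 0.918), with a median of −0.09 and a mean of 0.01. Cbx2 fell by 1.94. In VIP nuclei 1 was lower, Bmi1, and it lost its call without VIP replicate 2, at −0.88, and without excitatory replicate 2, at −0.95. None of the 8 mitochondrial-encoded genes is listed in the tables.

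DMRs of position 1 or 5 alone overlapped open chromatin of each neuron type less often than the pool of other single-position DMRs, though VIP peaks overlapped them in 8.21% and 9.37% of cases and DMRs of position 2 in 6.98%. H3K27me3 of excitatory neurons overlapped 29.1% of DMRs of position 1 alone and 19.9% of those of position 5, with odds ratios against the other positions of 3.91 (95% interval 3.65 to 4.19) and 2.81 (2.71 to 2.91). For position 2 it overlapped 5.01%, with an odds ratio of 0.334 (0.322 to 0.347). H3K27me3 also covered 33.5% of 525 genes higher in PV than in both others and 41.8% of 533 higher in VIP, against 13.6% of 900 higher in excitatory nuclei. Draws matched on gene length and excitatory TPM had medians of 25.0%, 31.0% and 13.7%. The longest UMRs lay on the sex chromosomes, at 47622611 to 53460608 of chromosome Y in VIP neurons (5.838 Mb), at 47631532 to 49761917 of Y in PV neurons (2.13 Mb) and at 149004782 to 149275615 of X in excitatory neurons (0.2708 Mb), and they held 0 ATAC-seq peaks of the same type. No coverage or methylation level was held, so a stretch with few usable reads cannot be told from an unmethylated one there.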
